A study of Mus musculus with 11 samples.

How the data were processed

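RNA from 11 mouse placental samples was labelled as biotinylated cRNA and hybridised to Affymetrix expression arrays, 1 array per sample: 4 KO, 4 WT and 3 TG. The values deposited by the authors are on the log2 scale, 1 value per probe set and array, from 0.66 to 13.61. The normalization method behind these deposited log2 values is not given in the sources used here. The upper quartile of the arrays ran only from 7.93 to 7.98, so the values had been brought to a common scale before deposit. The submitters' processing notes name limma without a version. Genotype, active copies and stage were taken from the labels.

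The table held 41345 probe sets, of which 23521 carried 1 gene symbol, 1820 carried several and 16004 none. Gene symbols came from the annotation supplied with the array. Of the probe sets with 1 gene, 23328 had an Entrez ID in the RefSeq gene table of assembly GRCm38.p6, and 0 symbols changed. That table served only for names and for which genes lie next to each other, since no genome build is named for the array, and no coordinates are given. Each of 22180 genes was represented by its probe set with the highest mean over all arrays; 1082 genes had more than 1. Genes with a mean signal at or above the percentile 40 of all probe sets, 5.78 log2, were tested, which left 15295. No background signal was available, so a difference from a group whose mean lies under 5.78 (Phlda2 in KO, Rps13 in WT and TG, Hba-x in WT, Prl7c1 in TG) is a lower bound of its size. Probe sets with several symbols or none were left out of the gene counts.

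The deposited values were used without further normalization. A linear model with 1 mean per genotype was fitted to all 11 arrays in limma 3.58.1 under R 4.3.3, and the contrasts KO minus WT, TG minus WT and TG minus KO were tested with moderated statistics, two-sided, without a trend. P-values were adjusted by the Benjamini-Hochberg method over the tested genes, and an adjusted p under 0.05 was called, with no fold minimum. All adjusted p-values of genes are from limma. Standard errors are those of the moderated fit. For Phlda2 an exact permutation test of the difference in means was run as well. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

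Fixed before the data were examined were the tests, the filter, the alternatives except those named below, 24 gene lists and the rule for naming genes. The lists cover the Phlda2 domain, placental prolactins, pregnancy-specific glycoproteins, placental Ceacam genes, placental cathepsins, glycogen metabolism, imprinted genes elsewhere, nutrient transporters, steroid synthesis, cell cycle, hypoxia, handling of tissue, and fetal sex. The others hold markers of spongiotrophoblast, glycogen trophoblast, giant cells, syncytiotrophoblast, fetal endothelium, red blood cells, decidua, uterine natural killer cells, macrophages, yolk sac endoderm and smooth muscle. By the naming rule, each comparison names Phlda2 and the 10 called genes with the largest rise and the 10 with the largest fall whose arrays do not overlap between groups. It further allows up to 4 members with the smallest p from each list with a call, Slc22a18, Cdkn1c, and the first 2 measured members of each marker list. Genes outside this rule are named as chosen after their values were seen, apart from the sex-linked genes.

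Lists with at least 4 tested genes were compared with all other genes by camera, with the preset correlation between genes of 0.01, adjusted over the 24 lists. Camera with an estimated correlation and fry were run beside it. None of the 35 list calls at the preset correlation was kept with an estimated correlation, and fry, which asks whether the genes of a list move one way on balance, kept 29 and called 4 further ones. Members were adjusted over all genes and over the list alone. A list score per array is the mean, over the tested genes of the list, of the log2 value minus the mean of that gene over all arrays. Lists share members: 6 of 9 spongiotrophoblast, 5 of 7 glycogen trophoblast, 5 of 7 giant cell, 6 of 18 prolactin, 3 of 6 cathepsin and 3 of 15 glycoprotein genes belong to another list.

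The KO and TG differences from WT share the WT arrays, which alone gives a correlation between them. Its size for unchanged groups was drawn 1000 times from residuals of the fit. The number of genes in overlaps of independent lists is the product of the list sizes over the number of tested genes.

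Alternatives were quantile normalization, centring on array medians, no filter and a filter at the percentile 60, the mean of all probe sets of a gene, a trended and robust variance model, array weights, a fit of only the 2 genotypes compared, the replicate number as a block, a covariate for Y-linked signal, leaving out each array in turn, and a slope over copies. Leaving out KO3 with KO4, leaving out KO1 with KO2, and the yolk sac score as a covariate were added after the data were seen. For the correlation of KO and TG responses only the filters, the genes called in TG against KO and the division of the WT arrays had been fixed, and its other alternatives, leaving out single arrays among them, were added after the data were seen. An alternative based on probe set name endings was not run, because the probe set IDs are numeric.

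The steps were tested on simulated data with the size and spread of these arrays, each gene drawn independently from a normal distribution. Correlation between genes and differences between arrays that move many genes together were not simulated. The rates that follow may therefore not hold for the real arrays. For KO against WT, 83.6% of genes changed by 0.5 log2 were called, and 97% of those changed by 1, among 15295 genes. For TG against WT these were 85.1% and 97%, and for TG against KO 83.6% and 95.5%. Of the calls, 5%, 5.7% and 5.3% fell on unchanged genes.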

Results

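Total RNA of mouse placentas at stage E16.5 was measured on 11 Affymetrix expression arrays. The samples fell into 3 genotypes that differ in the number of active copies of Phlda2, an imprinted gene expressed from the maternal allele. The knockout (KO) was inherited from the mother and left 0 active copies (4 arrays), the wild type (WT) had 1 (4 arrays), and a single-copy transgene (TG) brought the number to 2 (3 arrays). Arrays are named here by genotype and replicate number, as in WT3. The study's title poses the question of how Phlda2 acts on an endocrine compartment of the placenta. The design text names 2 independent litters, but the labels tie no array to a litter, so p-values measure the spread between these samples. The median signal per array lay between 6.218 and 6.29 on the log2 scale, pairs of arrays correlated at r = 0.984 to 0.993, and the small number of arrays limits the precision.

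Markers of yolk sac endoderm, a fetal membrane next to the placenta, varied more within genotypes than between them. The mean of the 16 measured markers, relative to the mean of all arrays, was 1.348 in KO1 and 1.149 in KO2 but -1.356 in KO3 and -1.382 in KO4. It was 0.848 in TG1 against -1.097 in TG2 and -1.224 in TG3, and it ran from -0.335 to 0.989 in WT. The plasma protein genes Afp and Ttr, at 12.68 ± 0.35 and 12.35 ± 0.38 in WT (SD, n = 4), stood at 12 ± 1.11 and 11.7 ± 1.27 in KO (SD, n = 4). Xist, the RNA of the inactive X chromosome, read 12.03 to 12.29 in KO3, KO4, WT3 and TG1 and 9.36 to 10.09 in the other arrays. Both Y-linked Uty and Eif2s3y were low in those same 4 arrays, so the female arrays were 2 of 4 in KO, 1 of 4 in WT and 1 of 3 in TG. KO3 and KO4 thus differed from KO1 and KO2 both in sex and in yolk sac signal.

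Phlda2 signal followed the number of active copies in every array. It was 5.16 ± 0.12 in KO (SD, n = 4), 6.85 ± 0.28 in WT (SD, n = 4) and 7.58 ± 0.38 in TG (SD, n = 3), and the 3 groups did not overlap. Against WT, Phlda2 fell by 1.69 ± 0.17 (SE) on the log2 scale in KO, at least a 3.23-fold decrease (limma adjusted p = 0.000846, two-sided exact permutation p = 0.0286). In TG it rose by 0.73 ± 0.18 (SE), 1.66-fold (limma adjusted p = 0.0308, two-sided exact permutation p = 0.0286, the smallest p that these arrays allow). The KO values lay between the 25.1 and 30.2 percentiles of all probe sets of their arrays, under the filter value of 5.78, so that differences from KO are lower bounds, and whether the probe set lies in the deleted part is not given in the sources used here. The TG call was lost without WT1 (log2 difference 0.68), without WT2 (0.62), without TG1 (0.51) and without TG3 (0.8), and in a fit of only WT and TG (0.73). Its adjusted p over all alternatives ranged from 0.0161 to 0.0832.

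Genes next to Phlda2 differed unevenly between genotypes. Slc22a18, the adjacent maternally expressed transporter gene, stood at 8.96 ± 0.16 in WT (SD, n = 4) and 8.98 ± 0.15 in KO (SD, n = 4), and rose by 0.7 ± 0.11 (SE) in TG (limma adjusted p = 0.00387). Whether the transgene carries a copy of Slc22a18 is not given in the sources used here. Cdkn1c, the neighbouring maternally expressed cell cycle inhibitor, differed by 0.11 ± 0.04 in KO (adjusted p = 0.187) and by -0.02 ± 0.05 in TG (adjusted p = 0.844). Kcnq1ot1, the paternally expressed non-coding RNA of the domain, fell by 0.32 ± 0.05 in TG (adjusted p = 0.00617). In KO it was higher by 0.27 ± 0.05 (adjusted p = 0.0167), a call lost without WT1 (0.061), WT2 (0.0519) or WT4 (0.0544). Of the 21 tested genes of the domain and its flanks, 1 rose and 1 fell in KO, and 6 rose and 4 fell in TG. Adjusted over the list alone, 1 rose and 1 fell in KO, and 8 rose and 4 fell in TG. As a group they did not pass the camera test in KO (adjusted p = 0.428; median 0.03, mean -0.02) or TG (0.217; mean 0.1), while fry, which does not compare them with other genes, called a rise in TG (adjusted p = 0.00231). Phlda2 itself, altered by design, is 1 of these 21 genes. Ascl2, a regulator of spongiotrophoblast formation that lies farther along the domain, fell by 1.01 ± 0.2 in TG (adjusted p = 0.0115) and differed by 0.58 ± 0.18 in KO (adjusted p = 0.0962).

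**Figure D1:**
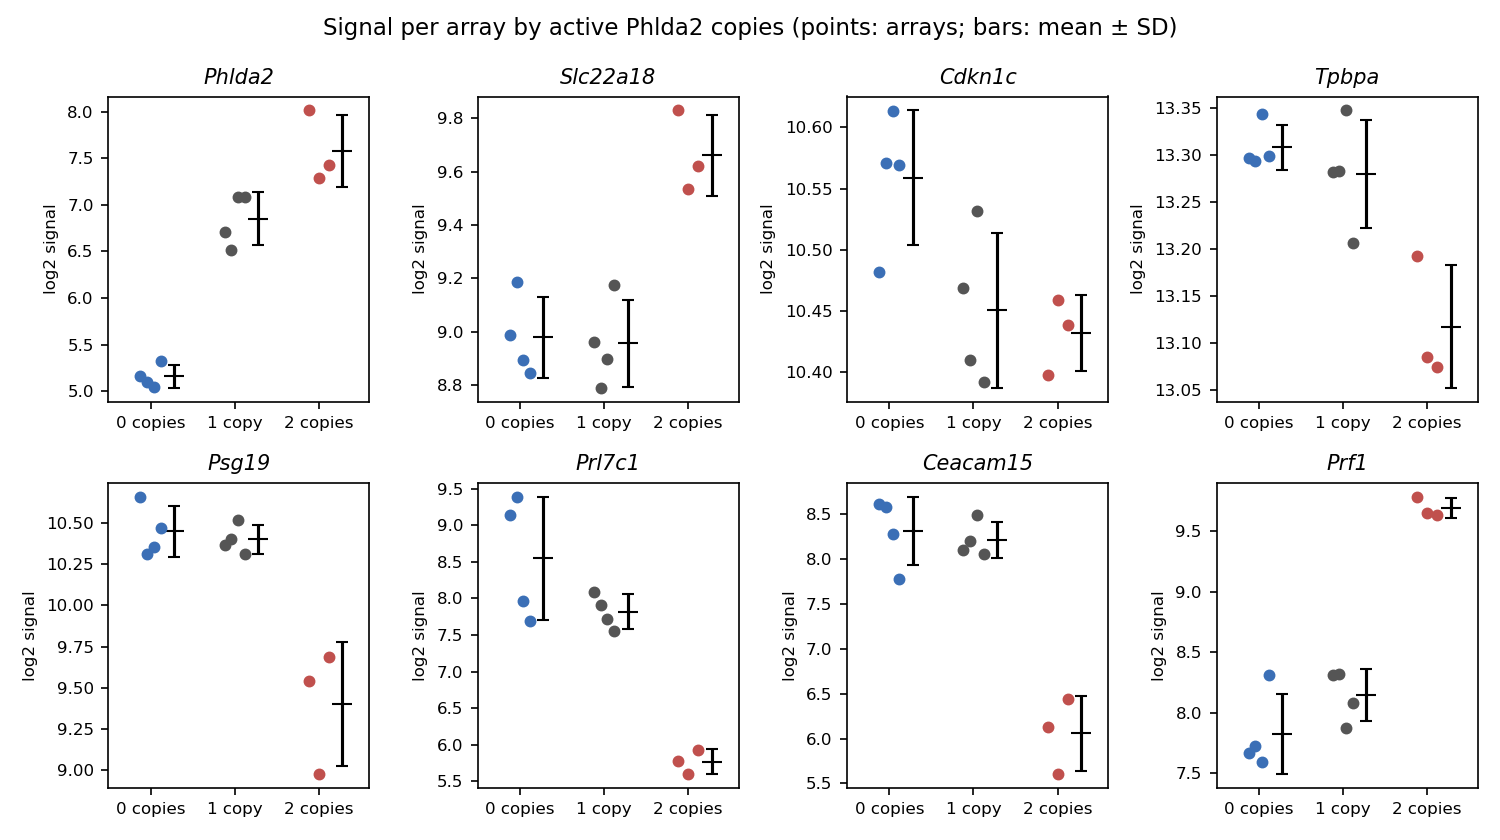
Log2 signal of 8 genes in each array (points) by the number of active Phlda2 copies, with the mean and SD of each genotype (bars). Phlda2 averaged 5.16, 6.85 and 7.58 with 0, 1 and 2 copies, and Psg19, Prl7c1 and Ceacam15 were lower in the 3 arrays with 2 copies than in all 8 others.

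The comparison of KO with WT asks what the loss of the active copy does. The probe set of Rps13, a ribosomal protein gene, had the largest difference of KO from WT. It read 4.48 ± 0.2 in WT and 8.02 ± 0.33 in KO (SD, n = 4 each), a log2 difference of at least 3.55 ± 0.19 (limma adjusted p = 2.16e-05). The WT signal of this probe set lay under the filter value of 5.78. The 54 other ribosomal protein genes had a median WT level of 9.07 and differed in KO by a median of 0.08. Whether this probe set measures Rps13 RNA in WT is not known, as no probe sequence was available. The embryonic globins Hbb-y and Hba-x rose by 1.18 ± 0.13 (adjusted p = 0.00155) and 1.07 ± 0.16 (adjusted p = 0.00597). Hsd11b1, which encodes an enzyme that interconverts glucocorticoids, fell by 0.98 ± 0.09 (adjusted p = 0.000686). Further falls were those of Ly6g6c (-1.19 ± 0.13), Elmod1 (-1.17 ± 0.09), Popdc3 (-1.07 ± 0.13), Npas2, a circadian transcription factor (-0.86 ± 0.11), and Corin, the protease that activates atrial natriuretic peptide (-0.7 ± 0.1). Further rises were those of Tmc5 (0.93 ± 0.09), the sodium channel subunit gene Scnn1b (0.8 ± 0.11), Nkain1 (0.74 ± 0.07) and the muscle actin gene Acta1 (0.74 ± 0.07).

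In all, 788 of 15295 tested genes changed in KO, 272 of them higher and 516 lower, and 8 changed by more than 2-fold. Ceacam-ps1 differed by -1.74 ± 0.34 (adjusted p = 0.0178), and its call was lost without WT1 (adjusted p = 0.0635), WT2 (0.055) or WT4 (0.0511), over a range of 0.00571 to 0.0635 for all alternatives. The number of changed genes was 475 without KO1, 212 without WT1, 318 without WT2 and 285 without WT4. Without KO3 and KO4, which had less yolk sac signal than KO1 and KO2, it was 915, and without KO1 and KO2 it was 799, both chosen after seeing the data. It was 1327 with the yolk sac score as a covariate and 469 without the filter on dim genes.

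Cell cycle genes rose together in KO. Of 33 tested, 12 rose and 0 fell over all genes, and 22 rose and 1 fell adjusted over the list alone (camera adjusted p = 8.25e-11; adjusted p = 0.464 with an estimated correlation). Cdk1, the mitotic kinase, rose by 0.5 ± 0.08 (adjusted p = 0.00926), and Mcm3, a subunit of the replicative helicase, by 0.38 ± 0.07 (adjusted p = 0.0149; 0.0509 without WT4). The list score of all 4 WT arrays, -0.161 to -0.134, lay below that of every KO array (0.005 to 0.207) and every TG array (0.068 to 0.145).

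Nutrient transporter genes fell in KO. Of 31 tested, 8 fell and 0 rose, and 11 fell and 2 rose adjusted over the list alone (camera adjusted p = 0.00233; adjusted p = 0.736 with an estimated correlation). The neutral amino acid transporter Slc1a4 fell by 0.59 ± 0.08 (adjusted p = 0.00284) and the glutamate transporter Slc1a1 by 0.42 ± 0.05 (adjusted p = 0.00154). Fetal endothelium markers were lower as a group (mean log2 difference -0.19; camera adjusted p = 0.00128; adjusted p = 0.81 with an estimated correlation), although only 1 of 15 was called on either adjustment. KO1 had the lowest endothelium score (-0.419), and without it the mean difference was -0.11. Neither call held without KO1 and KO2 together (adjusted p = 0.0595 for transporters and 0.324 for endothelium), and over the alternatives these p-values ran from 0.000385 to 0.736 and from 7.94e-07 to 0.81.

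Glycogen trophoblast markers were higher in KO (mean 0.31; camera adjusted p = 0.00801; adjusted p = 0.272 with an estimated correlation). Of 7 tested, Pcdh12, a protocadherin of glycogen cells, rose by 0.37 ± 0.07 (adjusted p = 0.0144; 0.0583 without WT1), and 2 rose adjusted over the list alone. Prl7b1 differed by 0.4 ± 0.1 (adjusted p = 0.0542) and Aldh1a3 by 0.9 ± 0.41 (adjusted p = 0.244). The Aldh1a3 signal was 10.32 and 10.27 in KO1 and KO2 but 9.06 and 8.03 in KO3 and KO4, against 8.52 ± 0.14 in WT (SD, n = 4). Its difference was 0.6 without KO1, 0.62 without KO2 and 1.36 without KO4, where it was called (adjusted p = 0.021). Placental cathepsins, lysosomal proteases of the trophoblast, were lower (mean -0.11; camera adjusted p = 0.022; adjusted p = 0.81 with an estimated correlation), with 2 of 6 falling and 4 adjusted over the list alone. Ctsr fell by 0.28 ± 0.05 (adjusted p = 0.0119). The cathepsin call was lost without KO3 (adjusted p = 0.0594), without TG2 (0.0796) and in a fit of only KO and WT (0.103).

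The endocrine families and the spongiotrophoblast, the layer that makes many placental hormones, showed little change after loss of Phlda2. The mean difference in KO was 0.03 for 15 tested genes of the pregnancy-specific glycoprotein family and 0.11 for 7 placental Ceacam genes. No member of either list was called by limma, over all genes or adjusted over the list alone, and 0 of each reached an unadjusted p under 0.05. Of 18 placental prolactins, Prl2c1 rose by 0.44 ± 0.08 (adjusted p = 0.0115) and the mean was 0.07 (camera adjusted p = 0.251); adjusted over the list alone, 3 rose and 1 fell. Of 9 spongiotrophoblast markers only Phlda2 itself fell, and Tpbpa and Tpbpb, which encode abundant proteins of that layer, differed by 0.03 ± 0.04 and -0.01 ± 0.06. Adjusted over the list alone, 1 of these markers fell and 1 rose (camera adjusted p = 0.92; median 0.03, mean -0.13). Phlda2, altered by design, enters that mean at -1.69.

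The other lists did not pass the camera test in KO (adjusted p = 0.218 to 0.873). Of 11 red blood cell markers, Hbb-y and Hba-x rose, and the mean was 0.23 (camera adjusted p = 0.218); adjusted over the list alone, 3 rose and 1 fell. Hbb-bh1, another embryonic globin gene, differed by 0.23 ± 0.15 (adjusted p = 0.4). The mean of 7 red cell genes other than embryonic globins and Car2 was -0.04 ± 0.08 (SE). Called members elsewhere were 2 of 24 glycogen metabolism genes (higher), 1 of 35 imprinted genes outside the domain, 1 of 12 steroid genes (Hsd11b1), 2 of 7 giant cell markers and 1 of 11 syncytiotrophoblast markers (all lower). Adjusted over the list alone these numbers were 2, 2 and 1, then 4 lower and 1 higher for giant cells, and 1 lower and 1 higher for syncytiotrophoblast. Of 20 immediate early and heat shock genes, which respond to tissue handling, 1 rose and 2 fell, and 2 rose and 4 fell adjusted over the list alone. Hspa1b, a heat shock protein 70 gene, fell by 0.54 ± 0.09 (adjusted p = 0.00783). No member was called among 19 hypoxia genes (4 at an unadjusted p under 0.05), 10 decidua markers (2), 9 uterine natural killer cell markers (1), 12 macrophage markers (0), 16 yolk sac markers (0), 9 smooth muscle markers (1) and 4 sex-linked genes (0). Adjusted over the list alone, 2 decidua markers fell. The median, mean and camera direction differed in sign for the macrophage, smooth muscle, steroid and handling lists, whose means were -0.04, -0.02, -0.01 and -0.03.

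The comparison of TG with WT asks what an additional active copy does. Endocrine genes of the placenta fell and genes of cytotoxic lymphocytes rose with 2 active copies. Ceacam15, of a placental branch of the carcinoembryonic antigen family, fell by 2.15 ± 0.22 (8.21 ± 0.2 in WT, SD, n = 4; 6.06 ± 0.42 in TG, SD, n = 3; limma adjusted p = 0.00115). Prl7c1, a placental prolactin, fell by 2.05 ± 0.36 (adjusted p = 0.00699), and the phospholipase gene Pla2g4d by 1.88 ± 0.2 (adjusted p = 0.00115). Gzmc and Gzmb, proteases of cytotoxic granules, rose by 1.88 ± 0.26 (adjusted p = 0.0027) and 1.8 ± 0.24 (adjusted p = 0.00235). Prf1, the pore-forming protein perforin, rose by 1.55 ± 0.16 (adjusted p = 0.00115).

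Among other genes with large changes, Ceacam-ps1 fell by 2.03 ± 0.36, Ccr1l1 by 1.67 ± 0.26, Cpxm1 by 1.67 ± 0.23, the sodium channel gene Scn9a by 1.65 ± 0.24 and the coagulation factor gene F11 by 1.6 ± 0.31. Fcrl6 rose by 1.66 ± 0.2 and Ctsg, a leukocyte protease, by 1.56 ± 0.24. The number of genes that changed in TG was 1570 of 15295, 937 higher and 633 lower (59.7% higher), with 63 changed by more than 2-fold. With each array centred on its median, 1373 were higher and 517 lower (72.6% higher). The number was 1003 without WT1, 849 without WT2, 757 without WT3, 980 without WT4, 987 without TG1, 886 without TG2 and 949 without TG3.

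Nearly all pregnancy-specific glycoprotein genes, which encode secreted trophoblast proteins, fell in TG. Of 15 tested, 14 fell, over all genes and adjusted over the list alone, with a mean difference of -0.87 (camera adjusted p = 7.09e-15; adjusted p = 0.132 with an estimated correlation). Psg19 fell by 1 ± 0.15 (adjusted p = 0.00333), Psg29 by 0.84 ± 0.14 (adjusted p = 0.0061) and Psg16 by 0.61 ± 0.1 (adjusted p = 0.00418). The estimated correlation between members was 0.822 in this list and 0.807 among placental Ceacam genes. Falls within either list are therefore not independent. All 7 placental Ceacam genes fell on both adjustments (mean -1.05; camera adjusted p = 9.51e-10; adjusted p = 0.132 with an estimated correlation), among them Ceacam14 (-0.95 ± 0.15) and Ceacam3 (-0.88 ± 0.12), which belongs to both lists under an older name.

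Of 18 placental prolactins 9 fell and 0 rose, and 13 fell adjusted over the list alone (mean -0.67; camera adjusted p = 6.08e-13; adjusted p = 0.102 with an estimated correlation). Prl5a1 fell by 1.5 ± 0.24 (adjusted p = 0.00464), Prl8a1 by 1.05 ± 0.16 (adjusted p = 0.0037), Prl3a1 by 1.04 ± 0.2 (adjusted p = 0.0107) and Prl2c1 by 0.94 ± 0.08 (adjusted p = 0.000793). TG2 had the lowest score of the 3 TG arrays in all 3 endocrine families: -0.738 against -0.438 and -0.35 for prolactins, -1.153 against -0.398 and -0.383 for glycoproteins, and -1.262 against -0.646 and -0.49 for Ceacam genes.

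Every one of the 9 spongiotrophoblast markers changed in TG, 8 falling and Phlda2 rising, with the same numbers adjusted over the list alone (mean -0.53; camera adjusted p = 1.58e-07; adjusted p = 0.132 with an estimated correlation). Of these, 6 also belong to another list. Flt1, whose product binds vascular endothelial growth factor, fell by 0.59 ± 0.07 (adjusted p = 0.00132), Prl8a8 by 0.46 ± 0.08 (adjusted p = 0.00608) and Tpbpb by 0.31 ± 0.07 (adjusted p = 0.0153). Tpbpa, among the brightest probe sets at 13.28 ± 0.06 in WT (SD, n = 4), differed by -0.16 ± 0.05 (adjusted p = 0.0474). That Tpbpa call was lost with median centring (adjusted p = 0.0958), with quantile normalization (0.0994) and without any 1 array other than WT4 and TG1, at most 0.141.

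Glycogen trophoblast markers were lower in TG (mean -0.49; camera adjusted p = 0.00319; adjusted p = 0.102 with an estimated correlation), with 2 of 7 falling and 3 adjusted over the list alone. Prl7b1 fell by 0.61 ± 0.11 (adjusted p = 0.00834). Aldh1a3, an enzyme of retinoic acid synthesis, fell by 1.79 ± 0.45 (adjusted p = 0.0314). The Aldh1a3 call was lost without any 1 of the WT and TG arrays (adjusted p = 0.0594 without WT1, 0.0778 without WT2, 0.0773 without WT3, 0.0623 without WT4, 0.0743 without TG1, 0.0882 without TG2 and 0.0793 without TG3). Giant cell markers were lower as a group (mean -0.31; camera adjusted p = 0.0196; adjusted p = 0.186 with an estimated correlation). So were cathepsins (mean -0.42; camera adjusted p = 0.00166; adjusted p = 0.193 with an estimated correlation). Among 7 giant cell markers 1 fell, and 3 adjusted over the list alone; among 6 cathepsins 2 fell, and 3 adjusted over the list alone. Ctsm, of both lists, fell by 1.31 ± 0.26 (adjusted p = 0.013) and Cts3 by 0.9 ± 0.15 (adjusted p = 0.00605), while Ctsq differed by -0.03 ± 0.04 (adjusted p = 0.758).

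Markers of maternal cells rose in the same TG samples. Uterine natural killer cells are lymphocytes of the decidua, the maternal lining that adjoins the placenta. Of their 16 listed markers 14 were on the array and 9 were tested. The tested ones include the granzymes Gzmb, Gzmc, Gzmd, Gzmf and Gzmg. Of 9 tested markers 8 rose and 1 fell, over all genes and adjusted over the list alone (mean 1.11; camera adjusted p = 4.21e-07; adjusted p = 0.132 with an estimated correlation). Gzmf rose by 1.53 ± 0.27 (adjusted p = 0.00732), Gzmg by 1.43 ± 0.24 (adjusted p = 0.00623) and Gzmd by 1.38 ± 0.21 (adjusted p = 0.00367). Il2rb, the member that fell, encodes a cytokine receptor subunit (-0.35 ± 0.1, adjusted p = 0.049; chosen after its values were seen). Of 10 decidua markers 7 rose and 1 fell, and 8 rose and 1 fell adjusted over the list alone (mean 0.29; camera adjusted p = 0.000637; adjusted p = 0.193 with an estimated correlation). Pgr, the progesterone receptor gene, rose by 0.78 ± 0.1 (adjusted p = 0.00174) and Hoxa10 by 0.57 ± 0.09 (adjusted p = 0.0044). Prl3c1 fell by 0.97 ± 0.22 (adjusted p = 0.0231), a call lost without WT1 (0.0506) or WT3 (0.0673), with a difference of -0.61 without TG2.

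Red blood cell markers rose in TG as well. Of 11 tested, 10 rose over all genes, and 10 rose and 1 fell adjusted over the list alone (mean 0.67; camera adjusted p = 3.83e-08; adjusted p = 0.102 with an estimated correlation). Hba-x rose by 1.3 ± 0.17 (adjusted p = 0.00238), Hbb-y by 1.27 ± 0.15 (adjusted p = 0.00129), the blood group gene Kel by 0.76 ± 0.1 (adjusted p = 0.00193) and Rhag, of the Rh complex, by 0.7 ± 0.08 (adjusted p = 0.00115). Cell cycle genes rose beside them: 13 of 33 rose and 0 fell, and 20 rose adjusted over the list alone (mean 0.26; camera adjusted p = 6.04e-09; adjusted p = 0.165 with an estimated correlation). The proliferation marker Mki67 rose by 0.83 ± 0.1 (adjusted p = 0.00192), cyclin A2 (Ccna2) by 0.77 ± 0.12 (adjusted p = 0.00424) and Nusap1 by 0.57 ± 0.08 (adjusted p = 0.00238).

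**Figure D2:**
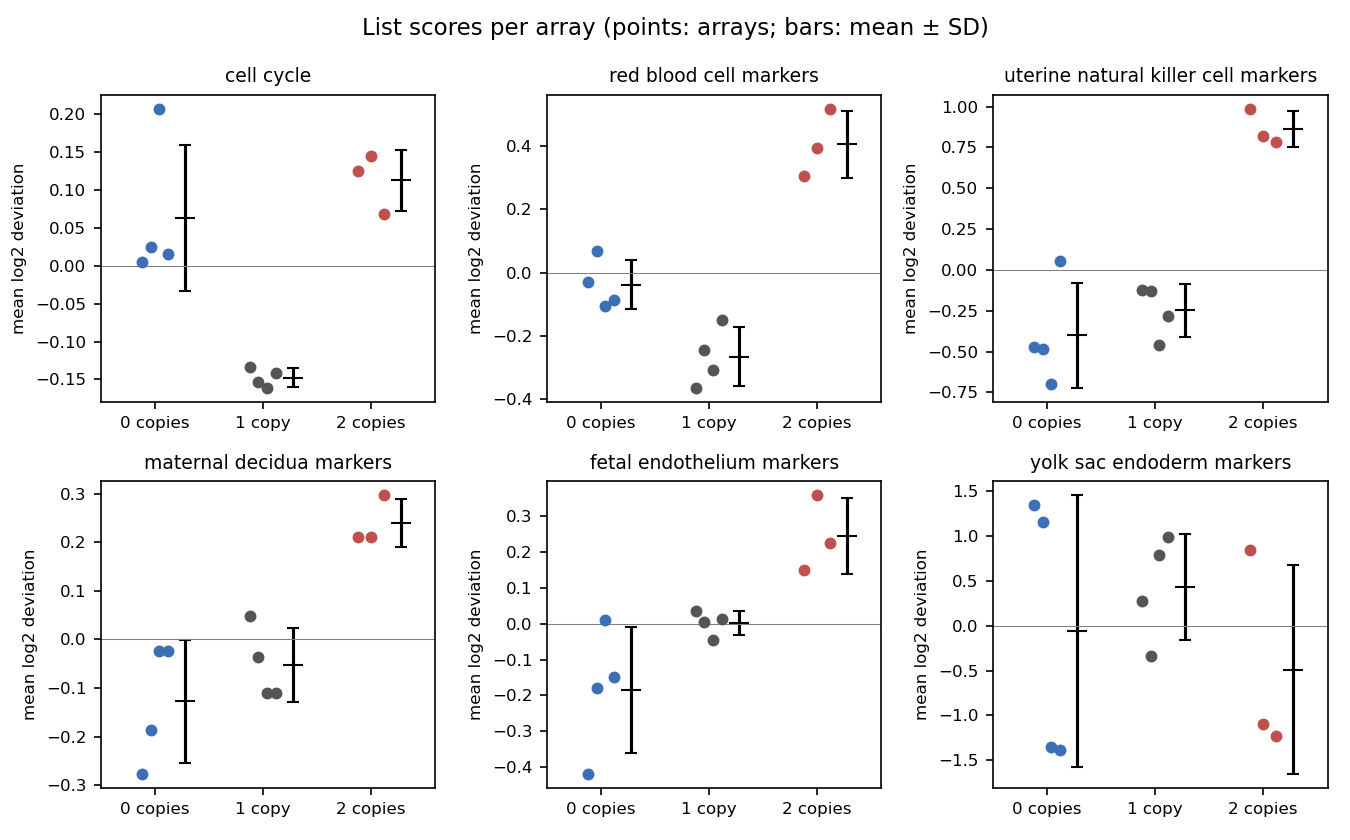
Mean log2 deviation of the tested genes of 6 lists from their mean over all 11 arrays, in each array (points) by the number of active Phlda2 copies, with the mean and SD of each genotype (bars). The uterine natural killer cell score averaged 0.86 in TG against -0.25 in WT, while the yolk sac score ranged from -1.38 to 1.35 within KO.

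Labyrinth markers, of the layer where fetal and maternal blood exchange nutrients, were higher in TG. Of 11 syncytiotrophoblast markers 4 rose and 0 fell, and 6 rose adjusted over the list alone (mean 0.23; camera adjusted p = 0.000452; adjusted p = 0.147 with an estimated correlation). Tfrc, the transferrin receptor gene that this list shares with the transporters, rose by 0.6 ± 0.08 (adjusted p = 0.0027) and stayed called in all alternatives. The calls of Gjb2 and Cebpa were lost without any 1 of the WT and TG arrays (limma adjusted p up to 0.116 and 0.131). That of Ly6e was lost without any of these except WT1 (up to 0.0916). Nutrient transporters rose in 7 cases and fell in 2 of 31, or 11 and 2 adjusted over the list alone (mean 0.12; camera adjusted p = 0.0012; adjusted p = 0.193 with an estimated correlation). Fabp4, a fatty acid binding protein gene, rose by 0.61 ± 0.08 (adjusted p = 0.00223), while the fatty acid transporter Slc27a6 fell by 0.72 ± 0.11 (adjusted p = 0.00464) and the carnitine transporter Slc22a5 by 0.43 ± 0.07 (adjusted p = 0.0057). Of 15 endothelium markers 2 rose, or 7 adjusted over the list alone (mean 0.24; camera adjusted p = 0.0012; adjusted p = 0.381 with an estimated correlation). The 2 called endothelium markers were Emcn and Kdr. Emcn was lost without any 1 of the WT and TG arrays (limma adjusted p up to 0.145). Kdr was lost without any of these except TG1 (up to 0.0916). With fry the endothelium list was not called (adjusted p = 0.0624). Cdh5, the endothelial cadherin gene, differed by -0.01 ± 0.05 (adjusted p = 0.879).

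Shifts of 4 further lists in TG passed the camera test but not every alternative. Imprinted genes outside the domain were higher (mean 0.12; camera adjusted p = 0.0456; adjusted p = 0.381 with an estimated correlation), with 5 of 35 rising and 1 falling, and 7 and 1 adjusted over the list alone. Gatm, which encodes a creatine synthesis enzyme, rose by 0.46 ± 0.06 (adjusted p = 0.00251). Glycogen metabolism genes were lower (mean -0.07; camera adjusted p = 0.0456; adjusted p = 0.23 with an estimated correlation), with 1 of 24 rising and 3 falling on both adjustments, including adjusted over the list alone. Hypoxia response genes were lower (mean -0.07; camera adjusted p = 0.0439; adjusted p = 0.327 with an estimated correlation). The collagen prolyl hydroxylase gene P4ha2 fell by 0.7 ± 0.1 (adjusted p = 0.0027), 1 of 2 of 19 that fell, also adjusted over the list alone. Yolk sac markers were lower (mean -0.92; camera adjusted p = 0.00319; adjusted p = 0.535 with an estimated correlation) with none of 16 called by limma on either adjustment and 0 at an unadjusted p under 0.05. The imprinted call was lost without KO4 (adjusted p = 0.0572), WT2 (0.139) or TG2 (0.209), with quantile normalization (0.0817) and with median centring (0.0629). That of glycogen metabolism was lost without KO3 (0.052), WT4 (0.0946), TG2 (0.154) or TG3 (0.106), and that of hypoxia without WT1 (0.0663), WT4 (0.0876) or TG3 (0.15). That of the yolk sac list was lost without TG3 (0.106), where its mean was -0.55, and its mean was -1.59 without TG1.

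No shift was called by camera for 5 lists in TG besides that of the domain. Of 12 steroid synthesis genes 3 rose and 2 fell, or 5 and 3 adjusted over the list alone (camera adjusted p = 0.931; median 0.02, mean -0.02). Hsd3b6, a hydroxysteroid dehydrogenase gene, rose by 0.86 ± 0.1 (adjusted p = 0.00117), and Cyp17a1, which encodes an enzyme of androgen synthesis, fell by 0.8 ± 0.11 (adjusted p = 0.00304). Hsd17b7 fell by 1.51 ± 0.31 (adjusted p = 0.0147), a call lost without TG2 (0.0559). Of 12 macrophage markers 1 rose and 2 fell, or 5 and 2 adjusted over the list alone (mean 0.35; camera adjusted p = 0.103). Of 20 handling genes (camera adjusted p = 0.376) 1 rose, and of 9 smooth muscle markers (0.281) 1 rose, also adjusted over the list alone. None of 4 sex-linked genes was called (0.643), with 0 at an unadjusted p under 0.05.

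**Figure D3:**
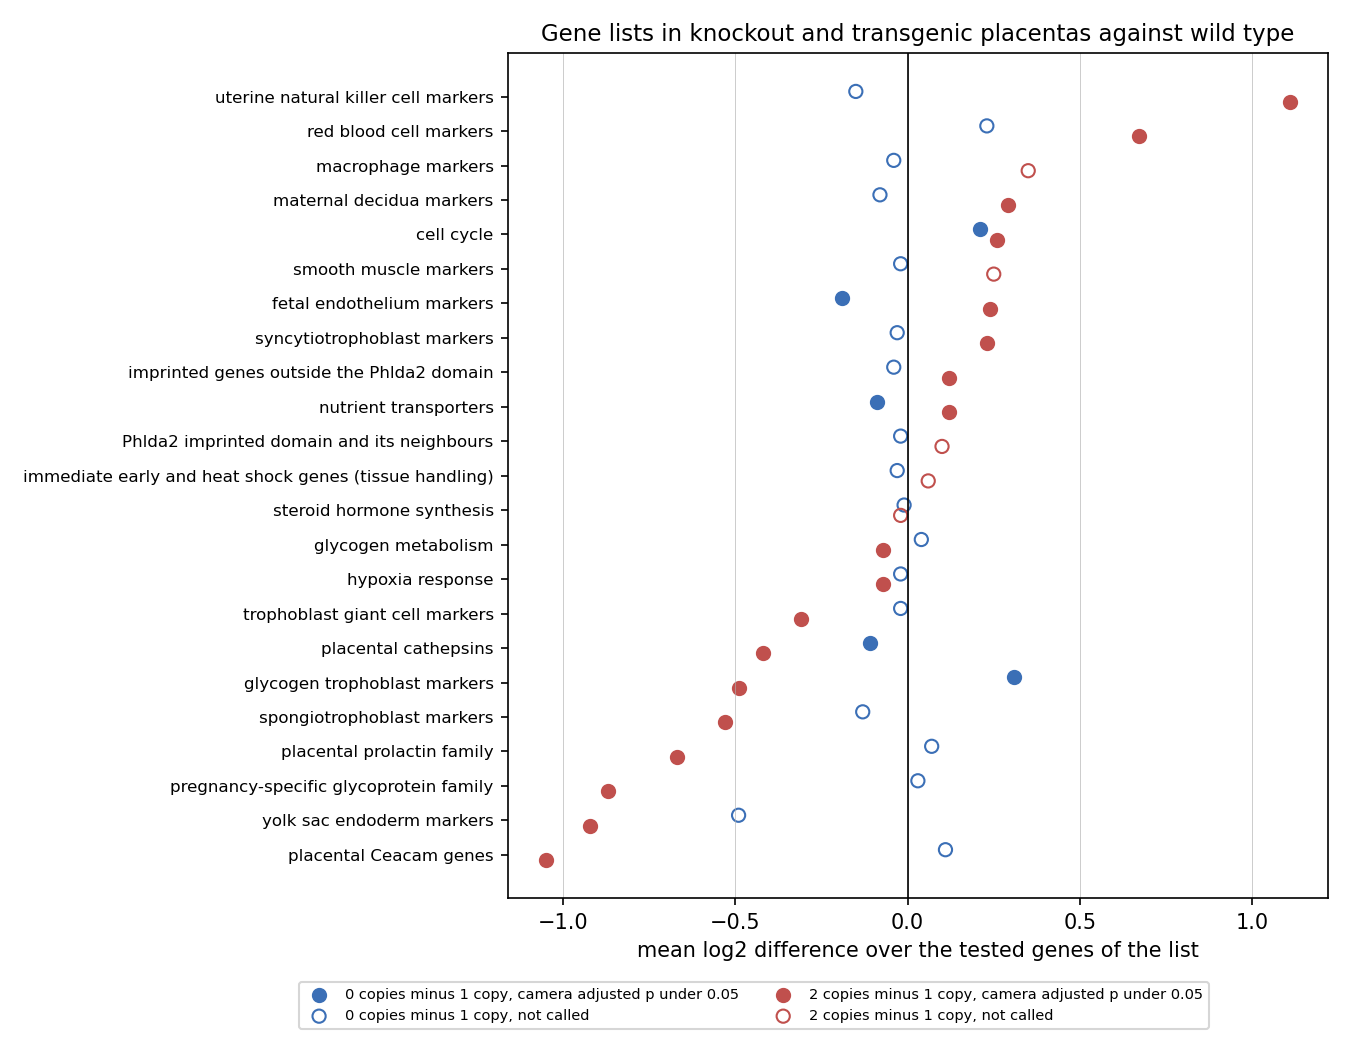
Mean log2 difference from WT (horizontal axis) of the tested genes of each fixed list except the sex-linked genes, in KO (blue) and TG (red), with filled points for lists that passed the camera test at the preset correlation. Placental Ceacam genes averaged -1.05 in TG and 0.11 in KO, and cell cycle genes 0.26 in TG and 0.21 in KO.

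The direct comparison of 2 with 0 active copies, whose differences leave out the WT means although the WT arrays enter the estimate of spread, held the most changed genes. Relative to KO, TG had lower Prl7c1 (-2.78 ± 0.36, limma adjusted p = 0.000397), Aldh1a3 (-2.69 ± 0.45, adjusted p = 0.00153), Pla2g4d (-2.41 ± 0.2, adjusted p = 5.85e-05) and Ceacam15 (-2.25 ± 0.22, adjusted p = 0.000112), with n = 3 and 4. Also lower were Scn9a (-2.08 ± 0.24), Hsd17b7 (-2.03 ± 0.31), the adenosine deaminase gene Ada (-1.86 ± 0.13), and Plac8 (-1.83 ± 0.18). Prl7c1 was higher in KO1 and KO2 (9.1 and 9.4) than in KO3 and KO4 (8 and 7.7), as was Hsd17b7 (10.1 and 10.2 against 9.5 and 8.6). Over the alternatives the difference ran from -3.5 to -2.06 for Prl7c1, from -3.57 to -1.82 for Aldh1a3 and from -2.57 to -1.48 for Hsd17b7. All 3 stayed called. Phlda2 was higher by at least 2.42 ± 0.18 (adjusted p = 2.85e-05, two-sided exact permutation p = 0.0286), Gzmc by 2.12 ± 0.26 (adjusted p = 0.000336), Gzmf by 1.96 ± 0.27 (adjusted p = 0.000553) and Prf1 by 1.87 ± 0.16 (adjusted p = 7.3e-05). Rps13, high in KO alone, was lower (log2 difference -3.48 ± 0.2, a lower bound in size; adjusted p = 9.87e-06).

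Between KO and TG 4076 of 15295 genes differed, 2594 higher and 1482 lower in TG (63.6% higher), and 134 by more than 2-fold. With each array centred on its median, 3258 were higher and 1166 lower (73.6% higher). A slope over 0, 1 and 2 copies in all arrays called 3756 genes, of which 3682 were among those 4076.

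The endocrine lists were lower in TG than in KO. Of 18 prolactins 15 were lower, of 15 glycoproteins 14, and of 7 Ceacam genes all 7, with the same numbers adjusted over the list alone. Camera adjusted p-values were 4.7e-09 for prolactins (adjusted p = 0.203 with an estimated correlation), 5.3e-10 for glycoproteins (adjusted p = 0.224 with an estimated correlation) and 3.46e-07 for Ceacam genes (adjusted p = 0.224 with an estimated correlation). Prl2c1 was lower by -1.38 ± 0.08 (adjusted p = 1.03e-05). Spongiotrophoblast markers were lower in 8 of 9 cases, also adjusted over the list alone (mean -0.39, or -0.24 without TG2; camera adjusted p = 7.3e-05; adjusted p = 0.224 with an estimated correlation). The other marker was Phlda2, altered by design, whose difference of 2.42 enters that mean. The median of the list was -0.65. Ascl2 was lower by -1.6 ± 0.2 (adjusted p = 0.000336) and Flt1 by -0.65 ± 0.07 (adjusted p = 0.000133). Of 7 glycogen trophoblast markers 5 were lower, or 6 adjusted over the list alone (mean -0.8; camera adjusted p = 0.000349; adjusted p = 0.104 with an estimated correlation). Prl7b1 was lower by -1.01 ± 0.11 (adjusted p = 0.000181) and Pcdh12 by -0.53 ± 0.07 (adjusted p = 0.000525). Glycogen metabolism genes were lower as a group (mean -0.12; camera adjusted p = 0.0297; adjusted p = 0.224 with an estimated correlation), with 5 of 24 lower and 2 higher on both adjustments. That call was lost without KO2 (adjusted p = 0.0536), TG2 (0.0699) or TG3 (0.0566). Pgm2, a phosphoglucomutase gene, was lower by -0.67 ± 0.08 (adjusted p = 0.00023).

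Transport and vessel genes were higher in TG than in KO. Of 31 nutrient transporters 18 were higher and 2 lower, or 20 and 3 adjusted over the list alone (mean 0.21; camera adjusted p = 3.66e-05; adjusted p = 0.224 with an estimated correlation). Slc1a1 was higher by 0.61 ± 0.05 (adjusted p = 5.05e-05), the iron exporter Slc40a1 by 0.46 ± 0.05 (adjusted p = 0.000154) and the arginine transporter Slc7a1 by 0.38 ± 0.04 (adjusted p = 0.000181). Of 15 endothelium markers 11 were higher and 0 lower, or 13 adjusted over the list alone (mean 0.43; camera adjusted p = 3.3e-05; adjusted p = 0.341 with an estimated correlation), among them Plvap (0.64 ± 0.11) and Sox18 (0.71 ± 0.12). Of 11 syncytiotrophoblast markers 6 were higher on both adjustments (mean 0.25; camera adjusted p = 0.00326; adjusted p = 0.224 with an estimated correlation), such as Ly6e, which encodes the receptor of syncytin A (0.52 ± 0.06, adjusted p = 0.000272).

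Maternal and red cell markers were again higher beside them. Of 9 uterine natural killer cell markers 8 were higher and 1 lower (mean 1.26; camera adjusted p = 7.3e-05; adjusted p = 0.224 with an estimated correlation). Of 10 decidua markers 7 were higher and 1 lower (mean 0.37; camera adjusted p = 0.00227; adjusted p = 0.286 with an estimated correlation), with Pgr up by 1.07 ± 0.1 (adjusted p = 8.13e-05). Of 11 red blood cell markers 8 were higher and 1 lower (mean 0.44; camera adjusted p = 0.00147; adjusted p = 0.224 with an estimated correlation), but Hbb-y differed by only 0.09 ± 0.15 (adjusted p = 0.707). These numbers were the same adjusted over the list alone. The red cell call was lost with a stricter filter at the 60th percentile (adjusted p = 0.175).

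The other lists did not pass the camera test between TG and KO (adjusted p = 0.0839 to 0.879). Of 33 cell cycle genes only 4 were called, all higher, on both adjustments (camera adjusted p = 0.879), Rrm2 by 0.51 ± 0.07 and Rrm1 by 0.62 ± 0.08. Imprinted genes outside the domain had 13 higher and 3 lower of 35 (camera adjusted p = 0.0839), or 16 and 3 adjusted over the list alone. Genes of the domain had 8 higher and 4 lower of 21, and steroid genes 4 higher and 3 lower of 12, with Hsd11b1 higher by 1.26 ± 0.1 (adjusted p = 4.44e-05). Adjusted over the list alone these were 9 and 5, and 4 and 3. Further numbers, higher and lower, were 2 and 2 of 6 cathepsins, 3 and 3 of 7 giant cell markers, 3 and 3 of 19 hypoxia genes, 2 and 1 of 20 handling genes, 4 and 2 of 12 macrophage markers and 1 and 0 of 9 smooth muscle markers. Adjusted over the list alone, cathepsins had 3 and 2, macrophages 6 and 2, and the rest the same numbers. No yolk sac marker and no sex-linked gene was called by limma, with none at an unadjusted p under 0.05. Median and mean differed in sign for cathepsins (0.07 and -0.31), steroid genes (0.03 and -0.01) and hypoxia genes (0.01 and -0.05), and the camera direction of the sex-linked genes (down) opposed their mean of 0.22.

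Whether loss and gain of copies moved genes in opposite directions was examined across genes, which are not independent replicates. Over all 15295 genes the KO and TG differences from WT had a correlation of -0.074 and a covariance of -0.00236. Unchanged groups simulated against the same WT arrays gave a mean correlation of 0.428, with 95% of draws between -0.467 and 0.925, and a mean covariance of 0.00657. With the WT arrays divided, 2 for each comparison, the correlation averaged -0.15, from -0.283 to -0.061. The sign rested on single arrays, left out here after the data were seen: the correlation was 0.102 without KO1, 0.015 without KO2, 0.012 without WT2 and -0.207 and -0.2 without KO3 and KO4, and it was 0.07 without the filter on dim genes. Numbers for independent lists are given beside the overlaps of called genes, but they leave out the shared WT arrays, which by themselves favour the same direction. Both lower in KO and higher in TG were 82 genes (31.6 for independent lists), including Slc1a1 and, chosen after their values were seen, Bmp4 and Pdgfc, and both higher in KO and lower in TG were 63 (11.3), including Prl2c1. In the same direction, 27 genes rose in both (16.7 for independent lists), among them Hbb-y and Hba-x, and 12 fell in both (21.4), among them Ceacam-ps1.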

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

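Tests of explanations in this part were chosen after the results were seen, apart from the splits of the arrays.

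Dixon's test for 1 value standing apart was applied to 380 groups of 4 values of named genes and list scores in KO or WT, and 23 stood apart where chance gives about 1 in 20, or 19. In KO4 these were Adm (8.46), Car2 (12.01), Ctsq (12.42), Gata1 (7.62) and Gzmd (10.81), and in KO1 Ly6f (5.56), Nkg7 (6.58), Slc1a1 (10.14) and the Ceacam score (0.54). In KO3 Tpbpa (13.34) and the cell cycle score (0.21) stood apart. WT1 stood apart for Ly6e (11.1), Popdc3 (8.99), Scnn1b (8.57), Slc7a1 (11.65) and Synb (10.87), WT2 for Nusap1 (6.3), Psg16 (10.34) and Smtn (10.37), WT3 for F11 (8.81), and WT4 for Hbb-bh1 (5.99), Hbb-y (7.58) and the cathepsin score (0.11). The 3 TG arrays are too few for this test.

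No comparison of genes used the 1820 probe sets with several gene symbols or the 16004 with none. Among a part of these, 8724 probe sets, limma called 156 (1.8%) in KO against WT, 720 (8.3%) in TG against WT and 1416 (16.2%) in TG against KO.

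Other splits of the arrays into groups of the same sizes were counted for each comparison. For the 788 genes of KO against WT and the 1570 of TG against WT, the real split was the only 1 of 35 with as many. The highest other split gave 0 in each. This cannot exclude chance, since no share below 1 of 35 was possible. The other splits also mix genotypes within a group, which widens the spread and lowers their counts. At an unadjusted p under 0.05 the real splits gave 3252 and 3962 genes and the highest other splits 1601 and 2545. For the 4076 genes of TG against KO the real split was again the only 1 of 35 with as many, under the same limits. The highest other split, with KO3 placed among the TG arrays, gave 815. At an unadjusted p under 0.05 these were 5760 and 4448.

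Cell cycle genes and the embryonic globins Hbb-y and Hba-x were higher in both KO and TG than in WT, while Hbb-bh1 rose in TG (0.94 ± 0.16) but differed in KO by 0.23 ± 0.15 (limma adjusted p = 0.4). More red cells of all kinds in the KO samples are argued against by the 7 other red cell genes, at -0.04 ± 0.08 (SE) where Hbb-y and Hba-x averaged 1.13 ± 0.13. A rise only of red cells with embryonic globins was not tested, and adult globins were not among the tested genes. More red cells in the TG samples stay open, as the 7 genes rose there by 0.58 ± 0.09, less than the 1.28 ± 0.14 of the globins by 0.7 ± 0.16. Chance values of the shared WT arrays are argued against for Hbb-y and Hba-x by limma, whose adjusted p over all tested genes was at most 0.00597 in either comparison, but remain open for the cell cycle list: its WT scores lay below those of all other arrays with an exact permutation p of 0.00303 over 330 splits, the smallest these can give, so that the adjusted value over 24 lists (0.0727) could not pass. A difference of stage or litter between WT and the other samples may also contribute and cannot be told apart from genotype, since the labels tie no array to a litter and the 27 genes that rose in both genotypes (16.7 for independent lists) do not decide it, as both comparisons share the WT arrays; an effect of both genotypes is the open biological explanation, untested.

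Granzymes were higher and spongiotrophoblast genes lower in TG than in WT. Dilution of all trophoblast RNA by maternal tissue is argued against by the syncytiotrophoblast list, which was higher by 0.23 ± 0.04 (SE). Its 11 genes differed by 0.01 to 0.6. Whether cells whose markers rose in TG also express these genes was not tested, which limits this argument. Evenly more decidual tissue stays open. Granzymes and perforin rose by 1.59 ± 0.25 and the 7 higher decidua genes by 0.51 ± 0.09, a difference of 1.08 ± 0.23. Both sets were picked for rising and differ in their WT levels, which could give unequal rises and was not tested. Fewer spongiotrophoblast cells in the TG placentas could give the falls, and this stays open. Over 27 genes the TG minus WT difference had a Spearman correlation of 0.353 with the WT level, for which no p-value was computed. It does not decide the question, since levels of different probe sets cannot be compared. Bright probe sets such as that of Tpbpa, at 13.28 in WT where the highest value of any probe set was 13.61, can also saturate.

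Rps13 was higher in KO alone, at 7.6 to 8.4 in KO, 4.24 to 4.67 in WT and 4.28 to 4.98 in TG. A general shift of ribosomal protein genes is argued against by the other 54, whose median difference was 0.08 (range -0.07 to 0.3). A chromosome segment carried along with the knockout allele remains open: of 307 genes between Rps13 and Phlda2 in gene order 16 were called (5.21%), against 5.15% of 14901 elsewhere (two-sided Fisher exact p = 0.896, odds ratio 1.01, 95% interval 0.568 to 1.68), and a segment could change few of its genes. A sequence variant or another transcript under the probe set stays open as well. The WT level of 4.48 lay below those of all 54 other ribosomal protein genes, whose median was 9.07, as this explanation would give. This does not decide the question, since levels of different probe sets cannot be compared, and no probe sequence was available. Loss of Phlda2 as the cause was not tested apart from these.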

How the results depend on the processing

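The settings with KO3 and KO4 or KO1 and KO2 left out, and the yolk sac covariate, were tests chosen after the result was seen, as were all settings of the correlation of KO and TG responses except the filters, the genes called in TG against KO and the division of the WT arrays. Over 24 settings, the called genes named, Phlda2 not counted, that were never lost were 21 of 41 in KO against WT, 57 of 81 in TG against WT and 81 of 95 in TG against KO, and none reversed. Genes that the stricter filter dropped were not counted as lost there. Of list calls, 2 of 5, 14 of 18 and 10 of 12 were never lost, apart from camera with an estimated correlation, which lost all 35, and fry, which lost 6 and gained 4: the domain list in TG against WT (adjusted p = 0.00231) and, in TG against KO, the domain (0.00525), imprinted (0.00582) and steroid (0.00834) lists. The domain list includes Phlda2 itself, which was altered by design. The 6 calls lost with fry were, in KO against WT, those of cathepsins (adjusted p = 0.072) and endothelium (0.234). In TG against WT they were those of endothelium (0.0624), glycogen metabolism (0.119), hypoxia (0.119) and yolk sac (0.351).

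Genes called in KO against WT numbered 788, but 469 without the filter, where more genes were tested, and 1327 with the yolk sac covariate, whose cause was not tested. They numbered 212 to 737 with 1 array left out. Genes called in TG against WT numbered 1570, and 757 to 1728 with 1 array left out. Those called in TG against KO stayed within 1.5 times 4076 in all settings, from 2746 to 4506. With the replicate number as a block the counts were 294, 825 and 3131. Residuals gave no sign that the numbers pair the arrays. The residual correlation of the 10 same-number pairs ran from -0.492 to 0.548, and only 3 exceeded 0.1. Its mean was -0.112, against 0.037 for the other pairs. This cannot exclude pairing, since other differences within genotypes, such as that of yolk sac signal, also enter the residuals.

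The Phlda2 difference of TG from WT was 0.73 in a fit of only those 2 genotypes, no longer called with fewer arrays behind its spread (adjusted p = 0.0571, over a range of 0.0161 to 0.0832), and ran from 0.51 to 0.87 with 1 array left out. The filter at the percentile 60 drops Phlda2 and gave no value. The correlation of KO and TG responses, -0.074, reversed without the filter (0.07) and without KO1 and KO2 (0.234), was -0.375 without KO3 and KO4 and -0.46 among genes called in TG against KO, a choice that by itself selects opposite signs, and ran from -0.207 without KO3 to 0.102 without KO1, also reversed without KO2 (0.015) and WT2 (0.012). It was -0.2 without KO4. The cause was not tested. The alternative based on probe set name endings was not run. Dim probe sets limit what can be seen, with Phlda2 in KO between the percentiles 25.1 and 30.2 of its arrays.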

Other observations

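Groups of genes sharing a symbol stem were tested after the results were seen, as were the genes named here.

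Inhibitor genes of the Serpinb family, which no fixed list holds, were enriched among genes higher in KO than in WT, 4 of 11 (adjusted Fisher exact p = 0.00746 over 255 stems). These were Serpinb9c, Serpinb9d, Serpinb9e and Serpinb9f. Serpinb9d rose by 0.66 ± 0.08 (limma adjusted p = 0.00239) and Serpinb9c by 0.47 ± 0.08 (adjusted p = 0.0126), and in TG against KO Serpinb9d was lower by -1.32 ± 0.09 with 6 of 11 of the family lower (adjusted p = 0.0105). Solute carriers, which include most genes of the nutrient transporter list and so in part repeat its result, were enriched among genes lower in KO, 30 of 296 (adjusted p = 2.07e-05). Outside that list these included the cation transporter Slc22a4 (-0.7 ± 0.06), Slc9b2 (-0.68 ± 0.08) and the phosphate transporter Slc20a2 (-0.5 ± 0.06). Of the 296, 84 were higher in TG than in KO (adjusted p = 0.000139). Genes of the Bmp family, which encode secreted signals and of which Bmp2 is a marker in the decidua list, were higher in TG than in KO in 7 of 10 cases (adjusted p = 0.0152), with Bmp4 at 0.97 ± 0.07 and Bmp8a at 0.75 ± 0.05.

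In TG against WT, surface antigen genes with the stem Cd were enriched among higher genes, 15 of 60 (adjusted p = 0.000577), with Cd96 at 0.86 ± 0.16, Cd24a at 0.81 ± 0.15 and Cd109 at 0.7 ± 0.09. MicroRNA genes were enriched among lower genes, 22 of 181 (adjusted p = 0.000375), with Mir669i at -0.78 ± 0.1, Mir669j at -0.77 ± 0.08 and Mir669e at -0.71 ± 0.06. These lie in an intron of the imprinted gene Sfmbt2, which fell by 0.21 (limma adjusted p = 0.0436). The Mir669 genes can thus share 1 transcript, and the enrichment counts them as independent although they may not be. Between TG and KO, semaphorin genes were lower in 8 of 17 cases (adjusted p = 0.00531), with Sema4c at -1.21 ± 0.13 and Sema3f at -0.96 ± 0.09, and Toll-like receptor genes higher in 7 of 9 (adjusted p = 0.00729), with Tlr4 at 0.68 ± 0.1. Rab genes were higher in 23 of 62 cases (adjusted p = 0.00729).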
